A study of Homo sapiens with 2 samples.

How the data were processed

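Chromatin immunoprecipitation followed by sequencing (ChIP-seq), which recovers DNA fragments bound by a chosen protein, was carried out on HL-60 cells made to overexpress C/EBPβ. HL-60 is a human leukaemia line of the myeloid lineage, and C/EBPβ is a basic leucine zipper transcription factor. The series holds 2 libraries, 1 immunoprecipitated with an antibody to C/EBPβ and 1 input library made without antibody. Neither has a replicate, so no test between samples was possible and all tests below run across the genes or peaks of 1 library. Their p-values and intervals cover counting error over genes or peaks only, and genes and peaks are not biological replicates. Cells without overexpression were not analysed here.

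Per the submitters' processing notes, BWA version 0.7.10, SAMtools and MACS2 version 2.1.1 were used with the human build hg19; the notes as given here attach no role or setting to any of them. Library construction, per the labels' protocols, included PCR amplification and gel selection of short fragments. The file analysed is the authors' deposited list of pairs of a peak and a RefSeq transcript, with the peak's chromosome, start and end, the transcript, a gene symbol, a distance and a score. The peak threshold, and whether the peaks were called against the input library, are not given in the sources used here. The distance runs from the transcription start to the middle of the peak: of 3743 transcripts with several peaks, 3742 gave a single start position (within 2 bases) when the distance was subtracted from the peak middle. Positive distances therefore point to higher hg19 positions whatever the strand of the gene, and upstream could not be told from downstream. The deposited score is a fixed function of that distance, exp(−(0.5 + 4 × |distance| / 3000)), which returned every score to within 4.99989e-13. It ranks closeness to a start and carries no peak height, enrichment or p-value. Read depth, and so the precision behind each peak, is unknown. Coordinates are printed as the file gives them, and whether starts count from 0 or 1 is not given in the sources used here.

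Transcripts were matched to a RefSeq gene table of GRCh38 for gene names only; none of its positions was used with the hg19 coordinates, and gene order in it was used only to look at neighbouring genes. Of 12532 transcripts, 12331 matched by accession, 129 by symbol, 55 by an older symbol, and 17 kept the deposited symbol. A total of 7 deposited symbols had been turned into calendar dates, as spreadsheets do with some gene names, and were recovered through their accessions where these matched. The background was the 19392 protein-coding genes on chromosomes 1 to 22 and X with a curated transcript in that table. It can hold genes absent from the transcripts the authors paired. Such genes count as not listed in every share and test below.

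A gene counted as listed when at least 1 peak was paired with 1 of its transcripts. For each of 15 gene lists, fixed before the data were examined, the share of members listed was compared with that of all other background genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. Shares carry exact (Clopper-Pearson) 95% binomial intervals. The 4 comparisons between groups of lists, the scan of gene families by shared symbol root (at least 10 members) and the comparison of chromosomes used the same test and were added after the data were seen. Peak widths (end minus start) near and far from a start were compared by a permutation test of the mean log2 width with 100000 resamples, also added after the data were seen, since the planned test of peak strength was not run. The named genes followed a rule set before the data were examined. It took the genes of the 10 peaks with the highest fold enrichment, or the highest score where no strength value exists. From each list it took up to 3 members with the strongest peak and up to 2 without a peak in alphabetical order. It also took the 5 genes with most peaks and the 5 C/EBP family genes CEBPA, CEBPB, CEBPD, CEBPE and CEBPG. The list has no strength value, so the score, which ranks closeness only, was used. The nearest peak thereby replaced the strongest after the file was seen. Any other named gene was chosen after its values were seen, and 1 gene that the rule names is not reported here.

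On simulated data over 19392 genes, 3 lists were set to a 70% share listed and all other genes to 26.5%. The list test recovered 75% of the raised lists over 100 runs and called 0.545% of unchanged lists. The raised lists were the primary granule, specific and tertiary granule and oxidase lists, of 19, 23 and 6 members. Their recovery was pooled, so 75% holds for no single list. It also does not describe shares below 70%, such as those seen for the granule lists. The alternatives were each peak given only to its nearest start, peaks within 1000 bases of a start, peaks above the median width, and 10000 random lists matched on the number of curated transcripts. Planned analyses of peak strength and of sequence motifs were not run, because the list as used here has no strength value and no hg19 sequence was used here. Analyses used Python 3.11.15, SciPy 1.17.1, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.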

Results

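Genome-wide binding of C/EBPβ near genes was examined in HL-60 cells overexpressing the factor, a design whose stated purpose was to find its target genes. The list held 7029 peaks in 17637 pairs with 12532 transcripts, all with a transcription start within 3000 bases of the peak middle. Of 19392 protein-coding genes, 5133 (26.5%, 95% interval 25.8 to 27.1) had at least 1 peak. A single peak was listed for 3585 of them, 2 peaks for 1106, 3 peaks for 310 and at least 4 peaks for 132. The genes with most peaks were RUNX1 and FOXP1, both transcription factor genes, with 9 each, followed by LMNA, which encodes nuclear lamins A and C, the antisense gene TSPOAP1-AS1 and the pseudogene ROCK1P1 with 8 each. TSPOAP1-AS1 shares peaks with the haematopoietic microRNA gene MIR142, which had 6 listed peaks. The peak at 56406548 to 56407946 on chromosome 17, for example, was paired with both. Peaks at all annotated starts of a gene were counted, and RUNX1, FOXP1 and LMNA had peaks at more than 1 start. ROCK1P1 is a copy of part of ROCK1, so reads can map to both. Median peak width was 229 bases, and the 10th and 90th percentiles of width were 150 and 440 bases.

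All 5 C/EBP family genes examined had listed peaks. CEBPB itself, the overexpressed gene, had 4 peaks on chromosome 20, at 48804029 to 48804523, 48807406 to 48807603, 48808502 to 48808648 and 48808852 to 48809094. Their middles lay at −2843, 385, 1456 and 1854 bases from the start at 48807119. CEBPB has no introns, so a construct carrying its coding sequence would give reads over that sequence in the gene. This need not cover all 4 peaks, and which of them overlap the coding sequence was not examined. CEBPA, which drives early granulocyte commitment, had 3 peaks on chromosome 19, the nearest at 33793088 to 33793458 and 197 bases from its start. CEBPE, needed late in granulocyte maturation, had 2 peaks on chromosome 14, at 23586329 to 23586500 and 23590043 to 23590275, both more than 1000 bases from the start. CEBPD had 1 peak, 460 bases from its start, and CEBPG had 1 peak, 714 bases wide and 316 bases from its start.

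**Figure D1:**
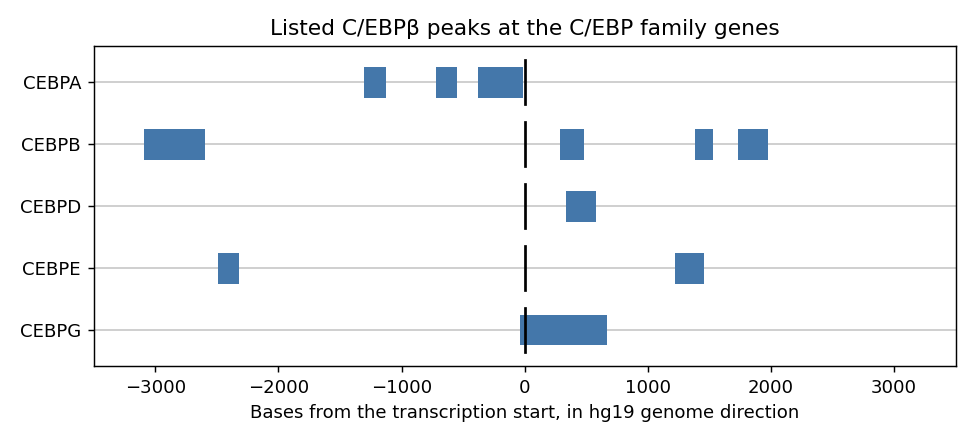
Listed C/EBPβ peaks (blue boxes, drawn to scale) at the 5 C/EBP family genes, on an axis of bases from the transcription start (black tick) in hg19 genome direction, whatever the strand. CEBPB has 4 peaks, CEBPA 3, CEBPE 2, and CEBPD and CEBPG 1 each.

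To describe where the listed peaks lie relative to genes, each peak was placed by its nearest start. Of the 7029 peaks, 4947 (70.4%, 95% interval 69.3 to 71.4) had their middle within 1000 bases of a start and 3727 (53.0%) within 500 bases, with a median distance of 445 bases. Among the 4717 peaks with a single start in the window, 64.8% (95% interval 63.4 to 66.2) lay within 1000 bases, against 33.3% for an even spread. The first 250 bases held 1488 of these peaks, 8.91 times the 167 in the outermost 250 bases. A total of 9 peaks lay exactly on a start, at the amino acid transporter gene SLC36A4, the natural killer receptor gene KLRC1, PPP4R3A, RPL23A, C17orf75, NME1, LINC01366, the chromatin reader gene BRD2 and the chemokine receptor gene CXCR3, and the next, at HNRNPH3, was 1 base away. Peaks within 1000 bases were slightly wider than the others, with medians of 231 and 225 bases and a difference in mean log2 width of 0.06 (permutation test, two-sided, p = 0.00016, 4947 and 2082 peaks). The window was set by the list, so these shares do not describe peaks farther from genes.

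**Figure D2:**
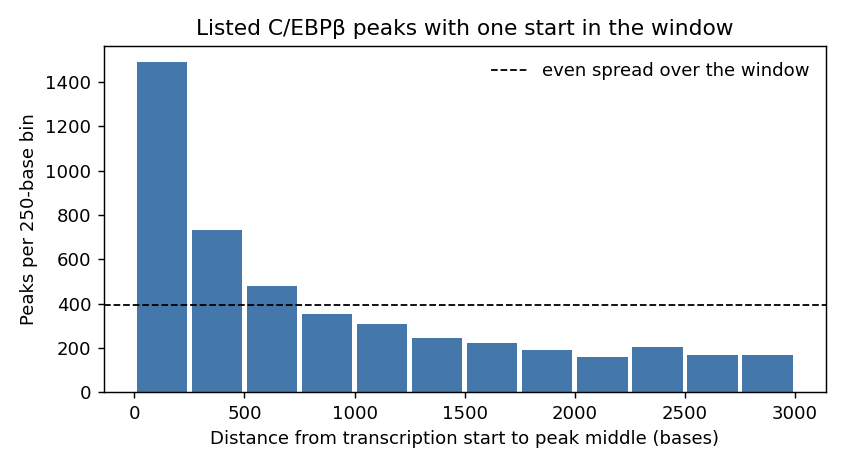
Number of listed peaks per 250-base bin of distance between peak middle and transcription start, for the 4717 peaks with a single start in the window. The dashed line marks an even spread; counts fall from 1488 in the first bin to 167 in the last.

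Genes of the ATF4 programme and the unfolded protein response, a set of stress genes that includes partners of C/EBP proteins, had the highest share of members listed among the 15 lists. Of 24 members, 20 (83.3%, 95% interval 62.6 to 95.3) had a peak. These included ATF3, a stress-induced transcription factor gene, 4 bases from its start, the amino acid transporter subunit gene SLC3A2 at 8 bases, and PHGDH, the first enzyme of serine synthesis, at −31 bases in genome direction. DDIT3, which encodes the C/EBP family member CHOP, had 5 peaks. ATF5 and NUPR1 had none listed. The share exceeded the 26.4% of other genes (odds ratio 13.9, Fisher's exact test, adjusted p = 1.39e-07).

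Myeloid transcription factor genes came next, with 22 of 30 listed (73.3%, 95% interval 54.1 to 87.7; odds ratio 7.67, Fisher's exact test, adjusted p = 8.33e-07). All 5 C/EBP family genes described above, the overexpressed CEBPB included, belong to this list and are counted among the 22. The list was not tested without them. JUNB had a peak 9 bases from its start. SPI1, which encodes PU.1, had 2, at 47398038 to 47398601 and 47400047 to 47400246 on chromosome 11, the second 19 bases from a start. At RUNX1 on chromosome 21, 4 peaks surrounded one start at 36260987 and 5 another at 36421595, the nearest at 50 bases. MYC had 6 peaks between 128746164 and 128751276 on chromosome 8, and GFI1, a repressor needed for neutrophil formation, had 4. BATF and CBFB were without a listed peak.

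Inflammatory mediator genes were listed for 18 of 30 members (60.0%, 95% interval 40.6 to 77.3; odds ratio 4.18, Fisher's exact test, adjusted p = 0.000417). The peak nearest a start was at S100A8, which encodes a subunit of calprotectin, at 5 bases. OSM, a cytokine of the interleukin-6 family, had 4 peaks with the nearest at 20 bases, and IL10 had 1 at −28 bases. Peaks were also listed at CXCL8, TNF and IL1B, at 51, 51 and 63 bases. The 12 members without a listed peak were CSF1, CSF2, CSF3, IL6, IL12B, IL18, CXCL2, CXCL3, CXCL5, PTGS2, NOS2 and LIF. Among myeloid receptors and adhesion molecules, 15 of 32 were listed (46.9%, 95% interval 29.1 to 65.3; odds ratio 2.46, Fisher's exact test, adjusted p = 0.0309). The members with the nearest peaks were the Fc receptor gene FCGR2A at −2 bases, the G-CSF receptor gene CSF3R at 34 and TREM1 at 35. IL6R carried one of the widest peaks, 1806 bases at 154377412 to 154379218 on chromosome 1, and ITGB2, the common β2 integrin subunit, had 5 peaks. CD33 and CD36 had none listed. The receptor list no longer passed when compared with random lists matched on transcript number (mean share 29.4%, adjusted p = 0.0848) or with peaks above the median width (odds ratio 2.50, Fisher's exact test, adjusted p = 0.0581); with the wider peaks the odds ratio was little changed.

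The 3 lists of granule and oxidase genes had shares above that of other genes but did not pass the adjusted threshold. Primary granule genes were listed for 9 of 19 (47.4%, Fisher's exact test, adjusted p = 0.0951), with the eosinophil ribonuclease gene RNASE2 at −22 bases, BPI at −39 and cathepsin G (CTSG) at 71. Neither of the near-identical defensin genes DEFA1 and DEFA3 was listed. Specific and tertiary granule genes were listed for 10 of 23 (43.5%, Fisher's exact test, adjusted p = 0.117), led by CRISP3 at −3 bases, the cathelicidin gene CAMP at −7 and TCN1 at 38; ARG1 and CD177 were not listed. Of the 6 NADPH oxidase subunit genes, 4 were listed (Fisher's exact test, adjusted p = 0.0764), among them RAC2 at 15 bases and NCF4 at −106. CYBB and NCF1 were not; NCF1 has near-identical pseudogenes. With each peak given only to its nearest start, the primary granule and oxidase lists passed (Fisher's exact test, adjusted p = 0.0473 and 0.0497). Their own shares did not change, at 47.4% and 66.7%, and the share of other genes fell to 23.4%.

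**Figure D3:**
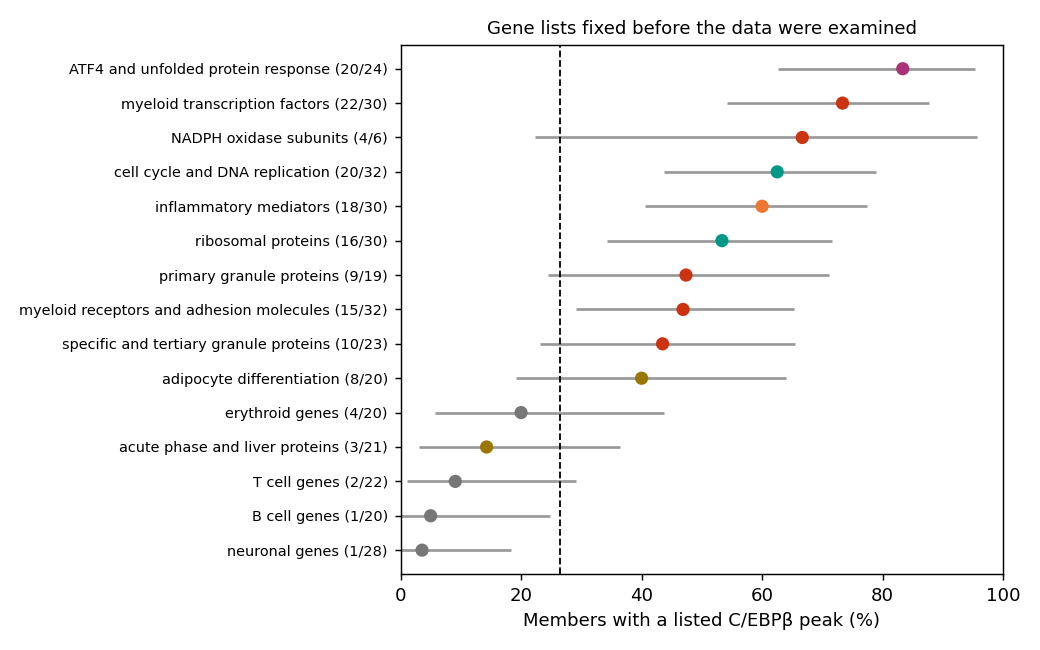
Share of each list's members with a listed C/EBPβ peak, in percent, with exact 95% binomial intervals (grey bars); counts stand beside the names and the dashed line is the 26.5% of all protein-coding genes. Red points are myeloid lists, orange inflammation, purple stress, green cell cycle and ribosomal, brown other tissues that use C/EBP factors, and grey other lineages; stress genes lie highest at 83.3% and neuronal genes lowest at 3.57%.

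Cell cycle and ribosomal protein genes were also listed more often than other genes. Cell cycle and DNA replication genes had 20 of 32 listed (62.5%, 95% interval 43.7 to 78.9; odds ratio 4.64, Fisher's exact test, adjusted p = 9.88e-05), among them the mitotic kinase gene AURKB at −2 bases, CCND2 with 5 peaks and the nearest at 19, and RB1 at 37. BUB1, CCNB1, CDK1, CDK2 and MKI67 were among the 12 without a listed peak. This list mixes drivers and inhibitors of cell division, and the inhibitor genes CDKN1A, CDKN1B, CDKN2C and RB1 were all listed. Ribosomal protein genes had 16 of 30 listed (53.3%, 95% interval 34.3 to 71.7; odds ratio 3.18, Fisher's exact test, adjusted p = 0.0082), with RPL3 at −23, RPL23 at 49 and RPL30 at −53 bases, and none at RPL10A or RPL11. The RPL3 and RPL23 peaks were also paired with small nucleolar RNA genes within the same loci. In the scan by symbol root, the RPL family passed (28 of 52, Fisher's exact test, adjusted p = 0.0015). The RPS family did not (15 of 43, Fisher's exact test, adjusted p = 0.469).

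Of the lists for other lineages, all of which had shares below that of other genes, the neuronal list passed the threshold. Neuronal genes had 1 of 28 listed (3.57%, 95% interval 0.0904 to 18.3; odds ratio 0.103, Fisher's exact test, adjusted p = 0.0102), the syntaxin gene STX1A, and none at CAMK2A or CNTNAP2. That call was lost with peaks above the median width (odds ratio 0.203, Fisher's exact test, adjusted p = 0.186). B cell genes had 1 of 20 (FCRL1, with 3 peaks; none at BANK1 or BLK) and T cell genes 2 of 22 (GATA3 and CTLA4; none at BCL11B or CD2), with adjusted p of 0.0715 and 0.117 by Fisher's exact test. Erythroid genes had 4 of 20 (GYPC, TFRC, KLF1 and EPOR; none at AHSP or ALAS2; Fisher's exact test, adjusted p = 0.62). Neither list from other tissues where C/EBP factors act passed the threshold. Acute phase and liver genes had 3 of 21 (Fisher's exact test, adjusted p = 0.343), at SERPINA1, HP and C3, with distances of 1982, −2584 and 2676 bases, and none at A2M or AGT. Adipocyte genes had 8 of 20 (Fisher's exact test, adjusted p = 0.234), with STEAP4 at 61 bases, KLF5 at −162 and PPARG at −186; of the other 5 listed members, 3 were the C/EBP genes CEBPA, CEBPB and CEBPD. ADIPOQ and CIDEA were not listed.

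The groups of lists were then compared with each other directly. The myeloid and inflammatory lists together had 78 of 140 genes listed (55.7%, 95% interval 47.1 to 64.1), against 8 of 90 (8.89%, 95% interval 3.92 to 16.8) for the erythroid, T cell, B cell and neuronal lists (odds ratio 12.9, Fisher's exact test, adjusted p = 2.95e-13). They also exceeded the liver and adipocyte lists, at 7 of 36 (19.4%, 95% interval 8.19 to 36.0, odds ratio 5.21, Fisher's exact test, adjusted p = 0.000267). Genes shared by both sides were left out of the liver and adipocyte group only. These were CEBPA, CEBPB, CEBPD and HP, all listed, and ORM1, not listed. Leaving them out lowers the liver and adipocyte share, while they still count in the myeloid and inflammatory group. Against the cell cycle and ribosomal lists, at 36 of 62 (58.1%, 95% interval 44.8 to 70.5), no difference was detected (odds ratio 0.909, 95% interval 0.473 to 1.73, Fisher's exact test, adjusted p = 0.878). The granule, oxidase and receptor lists alone had 38 of 80 genes listed (47.5%), which did not pass against the same 62 genes either (odds ratio 0.653, 95% interval 0.317 to 1.34, Fisher's exact test, adjusted p = 0.318).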

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

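All tests in this part were chosen after the results they bear on had been seen. The peak names carry running numbers, which the comparisons above do not use. The numbers rise with position on all 23 chromosomes of the list and reach 26024, so 18995 numbers belong to no listed peak and the 7029 listed peaks are 27.0% of the numbers. A list limited to a window around starts leaves numbers out in any case, so the count is not itself a finding; it would be the count of peaks away from starts if numbering was complete.

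On chromosome 8, the peak at TRIB1 spans 8178 bases (126441327 to 126449505), the widest in the list, and the 6 peaks at MYC nearly tile its promoter and first part. Peak numbers, listed and unlisted together, are also dense there, at 94.9 and 80.3 per Mb on either side of the TRIB1 peak. The genome as a whole had 8.89 per Mb. These are ranks 2 and 4 of the 261 stretches between neighbouring listed peaks whose numbers are at least 15 apart. Ranks 7 and 8 also lie on chromosome 8, beside NDRG1 and SLC45A4 at 77.0 and 71.1 per Mb. Both fall outside the 5 Mb from TRIB1 used below, in the rest of the chromosome. From general knowledge, not checked here, HL-60 carries amplified DNA around MYC, which could widen and multiply peaks of any kind. The 10 other listed peaks in the 5 Mb from TRIB1 had a median width of 275.5 bases (bootstrap interval 206 to 332), against 220.5 for the 226 peaks of the rest of the chromosome (permutation test, two-sided, p = 0.1281), which leaves amplification and strong binding unseparated; 27 peaks elsewhere were also wider than 1000 bases. Input coverage, which would decide it, was not analysed here, and no biological explanation was tested.

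The share of protein-coding genes listed differed between chromosomes, with 7 above and 4 below the rest (Fisher's exact test, adjusted over 23). Chromosome X was lowest at 11.5% (Fisher's exact test, adjusted p = 4.7e-26), chromosome 5 stood at 18.0% and chromosome 14 at 20.3%, while chromosomes 13 and 18 reached 37.4% and 37.3%. The 12 gene families called as listed less often are not the whole cause: without them, chromosome X stayed at 12%. That filter reached few of its genes, since 800 of 842 remained. Families with no member listed that did not pass, such as MAGEA (0 of 12) and GAGE (0 of 12), were kept. Unlisted numbers were sparse on chromosome X too, at 2.64 per Mb against 4.17 to 11.6 on the other chromosomes. Copy number of the cell line stays open. Losses in HL-60 on chromosomes 5, 9, 10, 14 and 17, with round borders, were recalled from general knowledge and not checked against a source, and the result depends on them. Unlisted numbers were 0.421 to 0.804 times as dense in those 5 stretches as in the rest of their chromosomes, but 10000 random placements on the same chromosomes gave a joint one-sided permutation p of 0.1616. Placements could overlap the stretch itself. Listed peaks were 0.301 to 0.448 times as dense in the 5 stretches, which was not tested. Listed peaks lie within 3000 bases of a start, and these densities were not adjusted for the number of genes in each stretch. By share of genes listed, chromosomes 5 and 14 were called lower. Chromosomes 9 (24.3%), 10 (24.5%) and 17 (25.7%) were not (Fisher's exact test, adjusted p = 0.366, 0.4 and 0.703). None of the stretches lies on chromosome X, 13 or 18, so the placement test does not bear on those chromosomes.

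No difference was detected between the shares of ribosomal and cell cycle genes and of myeloid and inflammatory genes listed. A candidate explanation is that promoters of widely expressed genes appear in the list in general, through open chromatin or through the high level of the factor. It stays open. Of 437 genes in 16 core protein complexes outside the 15 lists, 46.2% were listed, but the complexes were chosen after family shares had been seen and hold families already called higher, so that share is no support. Without those families, 82 of 218 genes were listed (37.6%, 95% interval 31.2 to 44.4), above the 26.5% of all genes but below the 55.7% of the myeloid and inflammatory lists (odds ratio 0.479, Fisher's exact test, p = 0.00105); leaving out called families lowers this share. All 437 genes gave an odds ratio of 0.683 against the myeloid and inflammatory lists, which did not pass (Fisher's exact test, p = 0.0526). No filter on called families was applied to those lists. Without peak heights, motifs or cells at the normal level of the factor, direct binding at promoters of widely expressed genes and non-specific recovery cannot be separated in this list. The myeloid lists still stood far above other lineages, which the explanation allows if those genes are inactive in HL-60; expression was not analysed here.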

How the results depend on the processing

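Of 60 alternative results for the 15 lists, 52 kept their direction and side of the threshold, 5 newly passed and 3 no longer passed; none changed direction. Only the nearest-start setting and counting equal coordinates once (7029 peaks, unchanged) were planned. With nearest starts, the primary granule (47.4% listed) and NADPH oxidase (66.7%) lists passed at unchanged shares, while the share of other genes fell to 23.4%. Within 1000 bases, oxidase genes (66.7%) passed above other genes and acute phase and liver genes (0%) below. Against random lists matched on transcripts (permutation test), B cell genes passed (adjusted p = 0.0317) and myeloid receptors did not (0.0848). With peaks above the median width, myeloid receptors (31.2%) and neuronal genes (3.57%) did not pass. These peaks left 2986 protein-coding genes. The odds ratio of granule, oxidase and receptor genes against cell cycle and ribosomal genes was 0.653 (Fisher's exact test, adjusted p = 0.318) and 0.468 within 1000 bases (adjusted p = 0.0541). That of all myeloid and inflammatory genes against them turned from 0.909 to 1.11 with nearest starts, neither past the threshold. The share of peaks near a start, 70.4%, was 53.0% within 500 bases, 64.8% for peaks with a single start and 71.5% for peaks above the median width. Without the 12 families listed less often, 9 of 11 chromosomes kept a call. Chromosome 2 (30.4%, odds ratio 1.15, Fisher's exact test, adjusted p = 0.0819) and chromosome 11 (26.2%, odds ratio 0.923, Fisher's exact test, adjusted p = 0.445) lost theirs. Chromosomes 15 (27.7%), 16 (27.4%), 20 (27.3%), 21 (31.2%) and 22 (26.5%), which had none, moved to the other side of the rest. Without genes that have only a locus number, all 11 kept a call and chromosome 22 moved (26.6%). With both left out, 9 kept a call and chromosomes 16 (27.6%), 20 (27.4%), 21 (33.5%) and 22 (26.5%) moved. Apart from those 2 lists with nearest starts, where a result changed, the cause was not tested. No peak strength was at hand, so settings on stronger peaks, and all motif settings, were not run. The planned wider promoter limit exceeds the 3000-base window and removes no peak, and gene length matching was not run because lengths came from another build. No paired analysis was possible because the 2 libraries have no replicates. Depth is unknown, so absence from the list is not absence of binding.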

Other observations

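All tests in this part were chosen after the data were seen. Among 276 gene families defined by a shared symbol root, 19 were listed more often and 12 less often than other genes (Fisher's exact test, Benjamini-Hochberg adjusted). Replication-dependent histone genes were among those listed more often: 15 of 17 H2AC genes (Fisher's exact test, adjusted p = 1.53e-05), 13 of 19 H2BC, 10 of 13 H3C and 10 of 15 H4C genes were listed, with the H2AC genes resting on 36 distinct peaks. These genes lie close together and resemble one another, so neighbours can share a peak, and reads can map to more than 1 copy. Coenzyme Q synthesis genes had 9 of 11 listed, proteasome core subunits of the PSMB family 8 of 11, RNA polymerase subunits of the POLR family 20 of 33, and mitochondrial ribosomal proteins 26 of 49 (MRPL) and 16 of 28 (MRPS). Large ribosomal subunit and related symbols (RPL) had 28 of 52. Other families of general use did not pass, among them small ribosomal subunit and related symbols (RPS, 15 of 43). Proteasome PSMD (5 of 14), COX (9 of 26), NDUFA (5 of 12), ATP (21 of 86) and MCM (3 of 10) did not pass either. The KLF family of zinc finger transcription factors had 11 of 18. Olfactory receptor genes (8 of 392), keratin-associated protein genes (2 of 94) and FGF genes (0 of 22) were among those listed less often.

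The single genes that follow were chosen after their values were seen and stand for no group. NFKBIA, which encodes the inhibitor of NF-κB, had 2 peaks, 1 of them 1153 bases wide. TNFAIP3 had 2 peaks with the nearest at −306 bases. The myeloid microRNA gene MIR223 had 2 peaks, the nearest at −732 bases. Peak numbers, listed and unlisted together, were dense beside CEBPA. Their 85.2 per Mb was rank 3 of the 261 stretches between neighbouring listed peaks whose numbers are at least 15 apart. By biotype, 195 of 1913 microRNA genes, 602 of 18330 long noncoding RNA genes and 5133 of 20056 protein-coding genes had a listed peak. The totals are those of the GRCh38 gene table, which can hold genes absent from the transcripts the authors paired. They are therefore not shares of genes that could have been listed.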
